A study of Mus musculus with 152 samples.

How the data were processed

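RNA was measured in 152 libraries of mouse glioma cells: 7 bulk libraries of 1000 sorted cells each and 145 single-cell libraries. Per the labels, tissue was dissociated with trypsin, cells were sorted as RFP positive or as RFP and Tlx-GFP double positive, RNA was extracted with the PicoPure kit and polyadenylated RNA was sequenced. Expected counts and TPM were deposited by the authors, each with 48795 gene entries and 92 spike-in sequences for every library. The first holds expected counts per gene, which the authors made with RSEM 1.3.0 against mm10 per the submitters' processing notes, with no normalization, and 1.70% of its values are not whole numbers. The second holds TPM, which the authors deposited after division by transcript length and scaling to the same total in each library. The notes also name DESeq2, without a version and without saying which deposited values it touched. The aligner, the annotation and any filter on cells or genes are not given in the sources used here. The spike-in sequences had 1 count in each of 5 libraries and 0 in the others, under the floor of 3 counts, and were left out. The deposited gene names include no GFP or RFP sequence, so the sorted colours could not be checked in the counts.

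Gene positions came from GENCODE M21 on GRCm38, the assembly also called mm10, which holds 48349 of the 48795 gene identifiers. Each library column was matched to its label by its title, and all 152 columns were used. For the 132 repeated symbols, the entry with the highest total was used for lists. Of the genes listed, Chi3l1 was not found.

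Expected counts were rounded. The population comparison in bulk used edgeR 4.0.16 in R 4.3.3 with TMM scaling, the count filter filterByExpr by population, and the quasi-likelihood F test with 5 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Standard errors of log2 changes were derived from that fit. Titles number the bulk tubes 1 to 4 in the stem group and 1, 2 and 4 in the tumour group. The tubes of equal number did not resemble each other after the population means were removed (r of -0.0291, 0.00327 and -0.0220 across genes), so the numbers were not treated as pairs, and a fit with them as blocks was an alternative. Single cells are not replicates of a population, so raw counts of cells were summed per mouse and population into 4 sums, and the same test was run with 2 residual degrees of freedom. The fit with the mouse as a block left 1. Cells needed at least 1000 genes with a rounded count of 1 or more, and all 145 passed.

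The 31 gene lists, 17 of pathways and 14 of cell types, were fixed before the data were examined, as were the comparisons, the tests and most alternatives. Lists with at least 3 tested genes were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation. Camera compares the genes of a list with all other genes. The genes named are the 8 key genes whatever their result, the 10 highest and the 10 lowest log2 changes among called genes without overlap between populations and with a mean log2 CPM of at least 3, leaving out gene models without a proper name, and up to 4 tested members per list with the lowest p. For the mouse comparison they are the 10 highest and 10 lowest ratios that had the same direction in both populations.

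For shares of cells, each cell was thinned at random to 100000 counts, and intervals are exact Clopper-Pearson intervals. Where a group held 1 to 3 counts of a gene, the ratio of counts is given with its counting interval. Clustering used Python 3.11.15, scikit-learn 1.9.0 and leidenalg 0.10.2, on log2 CPM of the 2000 most variable genes, 15 principal components, 15 neighbours and a resolution of 1. A cell was called rich in another cell type if it held at least 60% of that type's markers at 10 or more counts, a rule set after the data were seen. In the comparison of assays, called genes were set against 10000 random draws of genes of like expression, in 20 bins of level.

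The spread between libraries and their small number limit both designs. A bulk library held 3592406 to 4826680 counts and a cell 1477417 to 5984064 counts. Repeated bulk tubes differed by more than counting error, with a chi-square per degree of freedom of at least 4.08. The pipeline was tested on simulated data made from these libraries with known changes. The changes were placed in genes with a mean of at least 10 CPM, so recovery in genes of lower mean was not measured. Counts were drawn around the geometric mean, which is lower where a library or sum held few counts. The simulated level of a gene, mostly in the single-cell design, can thus lie under 10 CPM. In the bulk design it recovered 56% of 1.5-fold, 96% of 2-fold, 98% of 4-fold and 100% of 8-fold changes, with 7 false calls (3.85% of calls). In the single-cell design it recovered 0% of changes up to 4-fold and 10% of 8-fold changes, with 3 false calls (37.5% of calls).

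The alternatives for the bulk fit were DESeq2 1.42.0, DESeq2 size factors or library totals in edgeR, no count filter, a filter of 10 CPM in 3 libraries, limma on log2 TPM with an offset of 1 or 0.1 for genes of at least 1 TPM, the same without a filter, the replicate block, and leaving out each library. For the sums they were DESeq2, its size factors, no count filter, the mouse as a block, cells scaled to the median total, no cell filter, at least 2000 genes per cell, the code suffix and mouse as covariates, limma on log2 mean TPM, and leaving out each sum. The code suffix is the last part of the library code in the labels, with 4 values and no stated meaning. All bulk libraries share 1 value. A fit of the sums without marker-rich cells of other types was chosen after seeing the data. For clusters, resolutions of 0.5 and 2, 1000 variable genes and no cell filter were tried, and for shares, no thinning and a minimum of 5 counts.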

Results

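Polyadenylated RNA was sequenced from sorted cells of gliomas in 2 mice. The tumours arose in Tlx-GFP;Ntv-a mice given RCAS retroviruses that carry AKT, PDGFB and red fluorescent protein (RFP), so that cells infected with the RFP virus and their progeny are RFP positive. Tlx, listed as Nr2e1, is a nuclear receptor that keeps neural stem cells in a self-renewing state, and the Tlx-GFP reporter marks cells in which its promoter is active. RFP positive cells are called tumour cells here, after the labels, and RFP and Tlx-GFP double positive cells are called stem cells. The labels do not say whether GFP positive cells were kept out of the tumour gate. Bulk libraries of 1000 cells each came from mouse 1 alone, with 4 stem and 3 tumour tubes, and held 3592406 to 4826680 counts. The 145 single-cell libraries comprised 37 stem cells and 38 tumour cells of mouse 1 and 33 stem cells and 37 tumour cells of mouse 2. Each cell held between 1477417 and 5984064 counts and between 1559 and 3484 genes with a count. Intervals of count ratios and of shares of cells are 95% intervals for counting error only, since the reads carry no molecular identifiers and PCR copies of 1 molecule are not independent.

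The bulk libraries addressed how RFP and Tlx-GFP double positive cells differ from RFP positive cells of the same tumour. Stem tubes held more RNA of Tnc, Vim, Nes, Ccnb1 and Top2a and less RNA of Plp1 and Pdgfra, each of which passed as a single gene. Hmox1, which encodes the haem-degrading enzyme heme oxygenase 1, rose 13.9-fold, from 47.1 ± 16.8 CPM, counts scaled to the library total (mean ± SD, n = 3 tumour tubes), to 669 ± 125 CPM (n = 4 stem tubes). Tnc, which encodes the matrix protein tenascin C found around neural stem cells, rose 11.6-fold, from 11.0 ± 6.29 to 132 ± 19.4 CPM. Apod, which encodes a lipid carrier made by myelinating cells, was at 409 ± 316 CPM in the tumour tubes and 2.14 ± 1.03 CPM in the stem tubes, a log2 change of -7.62 ± 0.57 (SE). Plp1, the main myelin protein gene of oligodendrocytes, fell by 1.58 ± 0.10 on the log2 scale, from 858 ± 122 to 292 ± 34.0 CPM.

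Of 12920 genes tested, 911 passed an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 476 higher and 435 lower in the stem tubes, with 2624 at an unadjusted p under 0.05. DESeq2 called 1096 genes on the same counts, 900 of them among the 911. The values of the populations did not overlap for 2445 genes, or 18.9% of those tested, where chance gives 5.71%. Log2 CPM correlated at 0.954 to 0.962 across genes between tubes of a population and at 0.934 to 0.942 between populations, where genes are not independent replicates. On the second principal component of these tubes (15.6% of variance), tumour replicate 4 stood apart at 41.7, with tumour replicates 1 and 2 at -22.0 and -20.9. The tubes came from 1 animal, so the p-values measure the spread between tubes and not between mice. Without tumour replicate 2 the count was 576, and without tumour replicate 1, the library richest in Plp1 and Apod, it was 615.

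Nr2e1 itself (ENSMUSG00000019803, mm10 chromosome 10, 42561963 to 42583632) rose in the stem tubes, from 40.1 ± 5.58 to 61.1 ± 4.42 CPM, with a log2 change of 0.58 ± 0.14 and an adjusted p of 0.0187 by edgeR. The call was lost without stem replicate 2 (adjusted p = 0.0556) and without tumour replicate 4 (adjusted p = 0.0869), and the adjusted p ranged from 0.00629 to 0.246 over 16 alternatives. The genes that share their names with the retroviral inserts were also higher: Akt1 (ENSMUSG00000001729, chromosome 12, 112653821 to 112674884) rose by 0.90 ± 0.06 on the log2 scale to 1072 ± 67.9 CPM, with an adjusted p of 2.32e-07. Pdgfb (ENSMUSG00000000489, chromosome 15, 79995874 to 80014977) rose by 0.76 ± 0.08 to 194 ± 4.79 CPM, with an adjusted p of 2.31e-05. The counts do not separate the mouse genes from viral inserts of like sequence. Pdgfra (ENSMUSG00000029231, chromosome 5, 75152292 to 75198215), which encodes the receptor for PDGF and marks oligodendrocyte precursors, fell by 0.45 ± 0.04, from 3405 ± 67.1 to 2538 ± 71.7 CPM, with an adjusted p of 5.18e-06. Gfap, an intermediate filament gene of astrocytes and adult neural stem cells, rose 2.64-fold to 28.8 ± 6.25 CPM, with an adjusted p of 0.00392 that went up to 0.0662 over 16 alternatives, by limma on unfiltered TPM, where the call was lost. Mki67, a marker of cycling cells, rose 2.45-fold to 32.5 ± 5.83 CPM, with an adjusted p of 9.04e-04 that went up to 0.271 over 16 alternatives. Sox2, a transcription factor gene of neural progenitors, differed by 0.10 ± 0.10 with an adjusted p of 0.620, and Olig2, the oligodendrocyte-lineage factor gene, by -0.11 ± 0.06 with an adjusted p of 0.326.

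The 10 highest fold changes among genes whose libraries did not overlap were those of Ccl2, Ephb4, Emp1, Slc7a11, Aldh1a3, Hmox1, Kcnt2, Gdf15, Tnc and Pmaip1. Ccl2 (ENSMUSG00000035385), which encodes a chemokine that draws monocytes, had 470 counts over the 4 stem tubes and 1 over the 3 tumour tubes, a ratio of 335 per count sequenced with a counting interval of 59.9 to 13269. Ephb4 (ENSMUSG00000029710), an ephrin receptor gene, had 285 and 2 counts, a ratio of 102 with an interval of 27.9 to 843. Emp1 (ENSMUSG00000030208), a membrane protein gene, had 242 and 2 counts, a ratio of 86.3 with an interval of 23.6 to 717. The tumour counts of Ccl2 and Ephb4 all came from tumour replicate 2, so without it both had 0. Slc7a11 (ENSMUSG00000027737), which encodes the cystine transporter used in glutathione synthesis, rose by 4.89 ± 0.39 on the log2 scale to 56.3 ± 19.3 CPM, and by 5.61 without tumour replicate 4. Aldh1a3 (ENSMUSG00000015134), which encodes an enzyme of retinoic acid synthesis, rose by 3.91 ± 0.31 to 63.8 ± 9.04 CPM, and by 4.65 without tumour replicate 4. The potassium channel gene Kcnt2 rose by 3.71 ± 0.36, the stress cytokine gene Gdf15 by 3.56 ± 0.43 and Pmaip1, which encodes the cell-death protein Noxa, by 3.51 ± 0.40, or by 4.42 without tumour replicate 1.

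The 10 lowest fold changes were those of Apod, Trf, Adgrg2, Mal, Cdh18, Pcdhga12, Klhl4, Cnn2, Pcdha11 and Mgp. Trf (ENSMUSG00000032554), which encodes the iron carrier transferrin and is abundant in oligodendrocytes, had 137 ± 103 CPM in the tumour tubes and 1.87 ± 1.26 in the stem tubes, a log2 change of -6.25 ± 0.61. Apod and Trf varied between the tumour tubes, from 748 to 122 CPM and from 235 to 29.4 CPM in tumour replicates 1 and 4, and without tumour replicate 1 their log2 changes were -6.86 and -5.62. Adgrg2 (ENSMUSG00000031298), an adhesion receptor gene on chromosome X, did not vary in that way, with 109 ± 10.3 CPM against 1.69 ± 1.19 CPM and a log2 change of -6.03 ± 0.30. Mal (ENSMUSG00000027375), a myelin lipid-raft protein gene, fell by 3.93 ± 0.58, with a log2 change of -5.54 without stem replicate 4. The cadherin gene Cdh18 fell by 3.53 ± 0.59, with a log2 change of -4.54 without stem replicate 4. The actin-binding protein gene Cnn2 (ENSMUSG00000004665) fell by 2.83 ± 0.15, from 98.3 ± 4.26 to 14.1 ± 2.23 CPM. Mgp, which encodes matrix Gla protein, fell by 2.78 ± 0.29 and Klhl4 fell by 3.01 ± 0.43. The protocadherin gene Pcdhga12 fell by 3.22 ± 0.23, and Pcdha11 had a log2 change of -2.80 ± 0.39. Protocadherin transcripts share 3' exons, and 2 entries carry the name Pcdha11 and changed in opposite directions, so these values are uncertain.

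**Figure D1:**
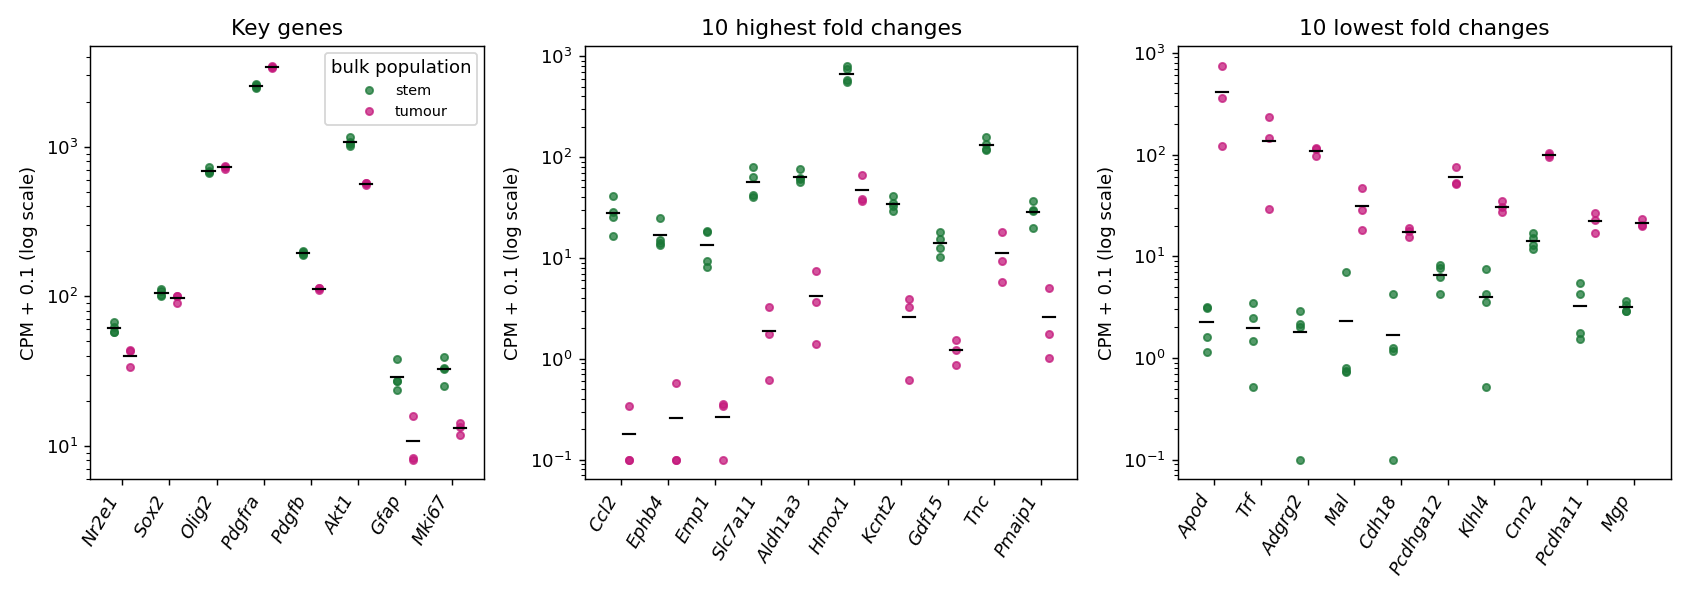
CPM of the 8 key genes and of the 10 highest and 10 lowest fold changes in each bulk library, on a log scale with a small offset, where points are tubes (4 stem, 3 tumour) and black bars are means. Hmox1 lies at 669 CPM on average in the stem tubes against 47.1 in the tumour tubes, and Sox2 and Olig2 overlap.

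Of the 31 gene lists fixed before the data were examined, 25 had at least 3 tested genes, and 8 differed from the other genes in the bulk tubes by limma camera with the preset correlation of 0.01. None of the 8 passed with an estimated correlation. Of 17 tested neural stem genes, 6 rose and 0 fell, or 9 and 0 adjusted over the list alone, with a median log2 change of 0.58 and a camera adjusted p of 3.60e-06 (adjusted p = 0.0744 with an estimated correlation). Nr2e1, whose reporter defined the stem gate, is 1 of the 6 and holds the median value. Part of the rise of this list therefore follows from the sort, and the list was not tested without Nr2e1. The intermediate filament genes Vim and Nes rose by 1.21 ± 0.11 and 1.15 ± 0.14, the stem cell factor gene Sox9 by 2.11 ± 0.43, or 2.74 without tumour replicate 4, and the Notch effector gene Hes5 by 0.78 ± 0.18. Hes5 lost its call without tumour replicate 2 (adjusted p = 0.0742) or 4 (adjusted p = 0.0662), with values of 0.00111 to 0.0833 over 16 alternatives. Of 27 genes of G2 and mitosis, 13 rose and 0 fell, or 17 and 0 adjusted over the list alone, with a mean log2 change of 1.34 and an adjusted p of 1.07e-12 (adjusted p = 0.157 with an estimated correlation). Among them, the mitotic cyclin gene Ccnb1 rose by 1.90 ± 0.28, the topoisomerase gene Top2a by 1.86 ± 0.30, the kinetochore gene Cenpf by 1.84 ± 0.29 and Ckap2 by 1.63 ± 0.20. Top2a, Cenpf and Ccnb1 lost their calls in 3, 3 and 1 of 16 alternatives (adjusted p up to 0.139, 0.647 and 0.0510), though not when a library was left out. The 24 S phase genes included 2 that rose, Rrm2 by 1.91 ± 0.31 and Dtl by 2.44 ± 0.60, or 3 adjusted over the list alone. Dtl lost its call without tumour replicate 2 (adjusted p = 0.0656) or 4 (adjusted p = 0.0791), with values of 0.00429 to 0.191 over 15 alternatives. As a list they did not pass (adjusted p = 0.0750), and they passed in the fit with the replicate number as a block (adjusted p = 0.0199) and without stem replicate 3 (adjusted p = 0.0244), with 0.244 as the highest value, from the estimated correlation.

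Of 8 tested mesenchymal genes, 3 rose and 0 fell, the same counts as adjusted over the list alone, with a median of 0.57 and an adjusted p of 0.0146 (adjusted p = 0.184 with an estimated correlation). They were Cd44, the hyaluronan receptor gene, by 2.85 ± 0.22, the protease inhibitor gene Timp1 by 2.83 ± 0.55, or 4.07 without tumour replicate 4, and S100a6 by 0.97 ± 0.23, which was not called without tumour replicate 2 (adjusted p = 0.0563, from 0.00356 to 0.0563 over 16 alternatives). Of 18 cholesterol synthesis genes, 6 rose and 0 fell, or 7 and 0 adjusted over the list alone, with a median of 0.22 and an adjusted p of 7.24e-04 (adjusted p = 0.305 with an estimated correlation). Cyp51, which demethylates lanosterol, rose by 0.75 ± 0.09, Nsdhl by 0.65 ± 0.14 and Hmgcs1, an early enzyme of the pathway, by 0.42 ± 0.07. Of 30 ribosomal protein genes, 3 rose and 0 fell, as they did adjusted over the list alone: Rps19, Rps3 and Rpl41, by 0.27 ± 0.06, 0.32 ± 0.08 and 0.27 ± 0.07. Their median was 0.13 with an adjusted p of 0.0426 (adjusted p = 0.652 with an estimated correlation). That call was lost when stem replicate 1 (0.163), stem replicate 2 (0.162), tumour replicate 1 (0.0678), tumour replicate 2 (0.0558) or tumour replicate 4 (0.0997) was left out, each value being the camera adjusted p without it. Rps3 and Rpl41 lost their calls without any 1 library other than stem replicate 3 (adjusted p up to 0.126 and 0.128), and Rps19 without tumour replicate 1 (adjusted p = 0.0683) or 4 (adjusted p = 0.0625), with values up to 0.0794 over 16 alternatives.

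Oligodendrocyte-precursor genes were lower in the stem tubes: of 16 tested, 11 fell and 0 rose, over all genes and adjusted over the list alone, with a median of -0.30 and an adjusted p of 1.66e-07 (adjusted p = 0.184 with an estimated correlation). Pcdh15 and the proteoglycan genes Bcan and Cspg5 fell, with log2 changes of -0.63 ± 0.08, -0.39 ± 0.05 and -0.29 ± 0.04. Of 11 oligodendrocyte genes, 8 fell and 0 rose, or 10 and 0 adjusted over the list alone, with a median of -0.77 and an adjusted p of 1.66e-07 (adjusted p = 0.184 with an estimated correlation). The myelin genes Mog and Mag fell, with log2 changes of -4.37 ± 0.77, or -6.87 without stem replicate 4, and -2.75 ± 0.48. Of 14 astrocyte genes, 7 fell and 2 rose, over all genes and adjusted over the list alone, with a median of -0.36 and an adjusted p of 0.0146 (adjusted p = 0.294 with an estimated correlation), and the list did not pass with the replicate number as a block (adjusted p = 0.0500, above the threshold before rounding) or without tumour replicate 4 (adjusted p = 0.0686). The neurotensin receptor gene Ntsr2, the aldolase gene Aldoc, the lipid carrier gene Apoe and the bicarbonate transporter gene Slc4a4 fell, with log2 changes of -1.03 ± 0.11, -0.57 ± 0.06, -0.60 ± 0.07 and -1.65 ± 0.21. The genes that rose were Gfap and Aqp4, the water channel gene, the latter by 1.44 and named here after its value was seen.

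Other lists did not differ from the remaining genes by camera, and their members split or were few. The heat-shock genes Hspa1a and Hspa1b rose by 2.44 ± 0.49 and 2.43 ± 0.50, or by 3.16 and 3.68 without tumour replicate 1, and Junb by 0.37 ± 0.11, which made 3 of 18 immediate-early genes higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.0771, and 0.00594 without tumour replicate 1). H2-D1, a class I histocompatibility gene, fell by 0.44 ± 0.07, the 1 of 7 interferon and histocompatibility genes that passed, with 2 lower adjusted over the list alone (camera adjusted p = 0.0677, 0.0290 without tumour replicate 1 and 0.0121 without tumour replicate 2). Among 19 genes of receptor and AKT signalling, 3 rose and 3 fell, or 4 and 5 adjusted over the list alone. Besides Akt1, Pdgfb and Pdgfra these included the growth factor receptor gene Fgfr3, which fell by 0.66 ± 0.13. Among 13 cell cycle inhibitor genes Cdkn1a rose by 0.45 ± 0.07 while Cdkn1b fell by 0.82 ± 0.18 and Ndrg2 fell by 0.24 ± 0.06, 1 and 2 genes adjusted over the list alone as well. The hypoxia target Vegfa fell by 0.47 ± 0.10, alone among 18 hypoxia and glycolysis genes, with 2 lower adjusted over the list alone. Of 12 Notch genes Hes5 alone passed, of 13 BMP and TGF-beta genes the BMP inhibitor gene Chrdl1 alone, by 1.38 ± 0.17, and of 26 oxidative phosphorylation genes Uqcrq alone, by 0.36 ± 0.09, with 1 gene each adjusted over the list alone too. When 1 library was left out, Junb kept its call only without stem replicate 2 or tumour replicate 1 (adjusted p up to 0.184) and Ndrg2 only without stem replicate 3 (up to 0.111). The calls of Cdkn1b (adjusted p = 0.0605) and Uqcrq (adjusted p = 0.0820) were lost without tumour replicate 2, those of Vegfa (adjusted p = 0.0528) and Uqcrq (adjusted p = 0.0745) without tumour replicate 4 and that of Uqcrq without stem replicate 4 (adjusted p = 0.0510). Over 16 alternatives the adjusted p went up to 0.222 for Cdkn1b, 0.115 for Vegfa and 0.0820 for Uqcrq, and Hspa1b was not called by DESeq2 (adjusted p = 0.0546, up to 0.0983). Of 13 Wnt genes 0 passed over all genes and 2 were higher adjusted over the list alone, with 5 hedgehog and 13 mitochondrially encoded genes at 0 by both adjustments.

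Markers of other cell types were few in the bulk tubes. Of 5 neuroblast genes, Tubb3 and Stmn1 rose by 1.28 ± 0.21 and 0.93 ± 0.20 and Dcx fell by 0.35 ± 0.10, and of 4 neuron genes, Nefm rose by 1.09 ± 0.29 while Snap25 fell by 0.49 ± 0.09 and Gad1 fell by 0.54 ± 0.11. These counts held adjusted over the list alone. When 1 library was left out, Dcx kept its call only without stem replicate 3 (adjusted p up to 0.179), Nefm only without stem replicate 3 or 4 or tumour replicate 2 (up to 0.127), and Stmn1 lost it without tumour replicate 2 (adjusted p = 0.0563, up to 0.0734 over 16 alternatives). Gad1 and Snap25 kept theirs there, but lost them in 3 and 1 of the 16 alternatives (adjusted p up to 0.170 and 0.0851). Of 9 microglia and macrophage genes 0 passed by either adjustment and 0 had a positive log2 change, with a median of -0.58 (camera adjusted p = 0.251, and 0.00945 without tumour replicate 4). Of 3 fibroblast genes Igfbp2 rose by 0.72 ± 0.07, also adjusted over the list alone. None of 4 endothelial and 2 mural genes passed by either adjustment. No ependymal, T cell, neutrophil or erythroid gene reached the count filter. The only sex-linked gene tested was Xist, with a log2 change of -0.22 ± 0.09 and 1 gene lower adjusted over the list alone, which passed over all genes with the replicate number as a block (adjusted p = 0.0317, up to 0.566 over 16 alternatives). The cell cycle inhibitor, Notch and hedgehog lists had positive medians and a camera direction of lower, and the fibroblast list had a negative median and a direction of higher. The mean was negative for cell cycle inhibitors and for the fibroblast list and positive for Notch and hedgehog.

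**Figure D2:**
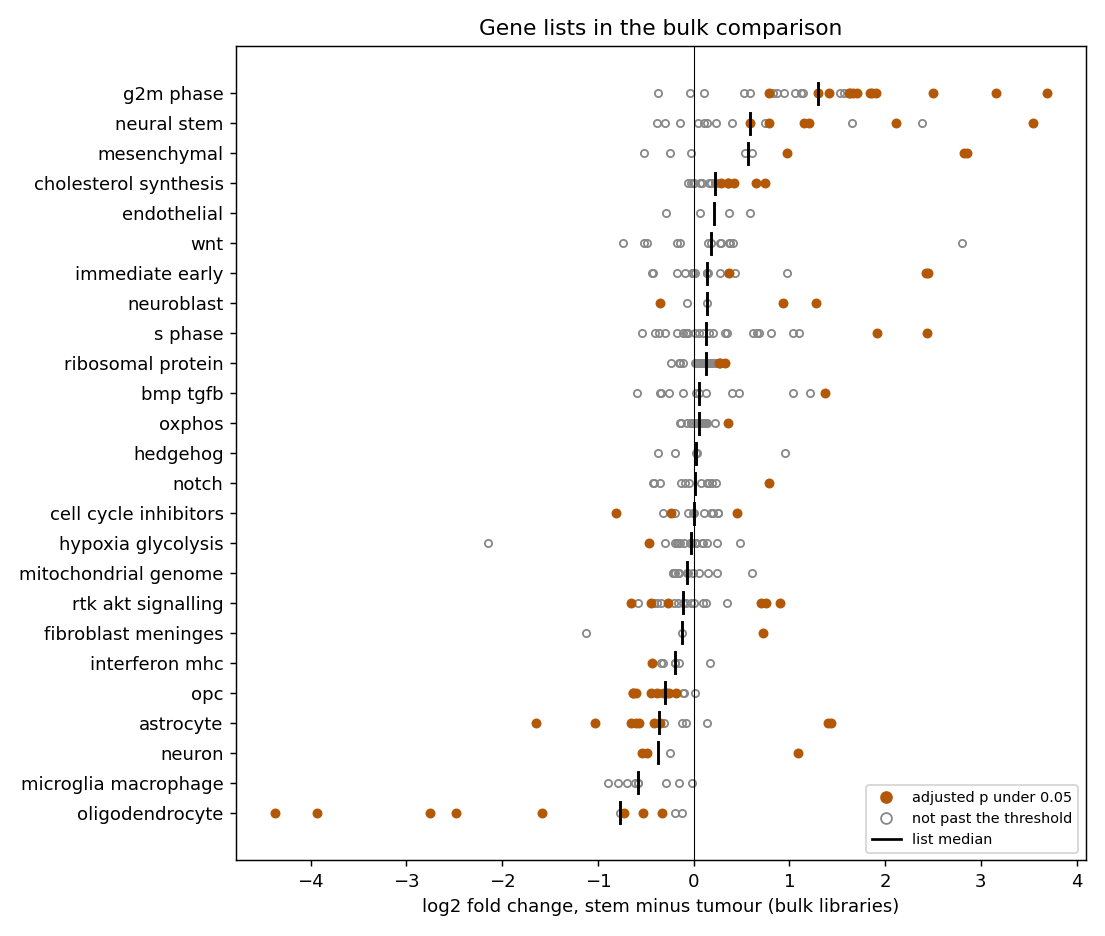
Log2 fold change, stem minus tumour, of each tested member of the lists with at least 3 tested genes, where filled points passed an adjusted p of 0.05 and black bars are list medians. The oligodendrocyte genes have a median of -0.77 and none lies above 0, and the oligodendrocyte-precursor genes have a median of -0.30.

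The single cells addressed the same question in 2 mice, with the counts of each mouse and population summed. Nr2e1 was higher in the stem sums of both mice, at 78.1 against 19.3 CPM in mouse 1 and 139 against 32.2 CPM in mouse 2, a log2 change of 2.11 ± 1.01 that did not pass (edgeR adjusted p = 1). Mki67 was lower in the stem sums, at 2.80 and 2.87 CPM against 134 and 97.9 CPM, which is opposite in direction to the bulk tubes. Its counts came from 1 and 3 stem cells and 1 and 2 tumour cells with 10 or more counts in mice 1 and 2, and its log2 change of -5.34 ± 1.23 did not pass (adjusted p = 1). By DESeq2 Nr2e1 passed with an adjusted p of 0.0439 and Mki67 with 4.43e-15, the lowest of 14 alternatives for each, with 1 as the highest. Pdgfra was at 2581 and 3623 CPM in the stem sums and 2489 and 2576 CPM in the tumour sums, and Akt1 at 626 and 522 CPM against 531 and 498 CPM. Hmox1 was at 139 and 0.018 CPM in the stem sums of mice 1 and 2 and at 35.2 and 33.0 CPM in the tumour sums. Tnc was at 128 and 0 CPM in the stem sums and at 0.006 and 32.8 CPM in the tumour sums. Both were higher in the stem sum of mouse 1 and lower in that of mouse 2, with at most 6 cells of any sum at 10 or more counts.

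None of 11773 genes passed in the sums by edgeR, with 536 at an unadjusted p under 0.05, 0 in the fit with the mouse as a block and 169 at an unadjusted p under 0.05 there. DESeq2 called 891 genes, 406 higher and 485 lower. Of these, 346 had 0 counts in both sums of a population, and 562 (63.1%) had at least 50% of their counts in 1 cell. The sums did not overlap for 3590 genes, or 30.5%, where chance gives 33.3%. The biological coefficient of variation was 1.62 between the sums and 0.162 between the bulk tubes, and in simulated data of this design 10% of 8-fold changes were recovered. The last digits of the library codes have no stated meaning. Within each mouse no value of these digits held both populations. Differences between the stem and tumour cells of a mouse therefore cannot be separated from differences between these values. In a fit with them and the mouse as covariates 0 genes passed, with 75 at an unadjusted p under 0.05.

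No gene list passed in the sums, over all genes or adjusted over the list alone, in either the simple fit or the fit with the mouse as a block. Of 18 cholesterol synthesis genes, 14 had a positive log2 change, with a median of 0.67 and a camera adjusted p of 0.453, and 0.0437 without tumour mouse 1. Hmgcs1 was at 624 and 294 CPM in the stem sums and 197 and 236 CPM in the tumour sums of mice 1 and 2, and its log2 change of 1.11 ± 0.52 did not pass. All 7 tested oligodendrocyte genes had a negative log2 change, with a median of -2.72 and an adjusted p of 0.557, and 9.10e-07 without tumour mouse 1, which leaves the tumour cells of mouse 2. That sum holds the 2 oligodendrocyte-rich cells described below, and Plp1 was at 591 and 384 CPM in the stem sums and at 1026 and 5670 CPM in the tumour sums of mice 1 and 2. The microglia list (adjusted p = 0.912) passed without tumour mouse 1 at 2.90e-08 and the mural list, with 1 gene tested in all sums, at 0.0437, while the erythroid list, with 0 tested in all sums, passed at 2.40e-06 without stem mouse 1. Medians were 0.76 for 13 neural stem genes (9 positive), 0.32 for 26 S phase genes, -0.18 for 21 G2 and mitosis genes, 0.17 for 16 oligodendrocyte-precursor genes and 0.02 for 11 astrocyte genes. They were -0.37 for 11 cell cycle inhibitors, 0.10 for 11 Notch, 0.16 for 8 BMP and TGF-beta genes, and 6 of 9 Wnt genes had a positive log2 change with a mean of 1.36. For 14 hypoxia and glycolysis genes the median was -0.52, for 26 oxidative phosphorylation genes 0.22, for 13 mitochondrially encoded genes 0.10, for 14 immediate-early genes -0.40 and for 6 interferon genes 0.56. For 4 mesenchymal genes it was 0.95, for 30 ribosomal protein genes 0.14, for 18 receptor and AKT genes -0.19, for 4 neuroblast genes -0.31, for 4 neuron genes -0.77 and for 4 sex-linked genes -1.12. The hedgehog, endothelial, mural and fibroblast lists had 2, 2, 1 and 1 tested genes with medians of -1.95, 0.27, 0.31 and 0.53, and the ependymal, T cell and neutrophil lists had 0. The mean or camera direction had the other sign from the median for the Notch, BMP and TGF-beta, mesenchymal, oligodendrocyte-precursor and neuroblast lists.

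After each cell was thinned to 100000 counts, Nr2e1 was detected in 12 of 37 stem cells of mouse 1 (32.4%, 18.0% to 49.8%, exact Clopper-Pearson) and 15 of 33 of mouse 2 (45.5%, 28.1% to 63.6%). It was detected in 2 of 38 tumour cells of mouse 1 (5.26%, 0.644% to 17.7%) and 2 of 37 of mouse 2 (5.41%, 0.661% to 18.2%). Without thinning the shares were 45.9% and 60.6% of stem cells and 5.26% and 13.5% of tumour cells. With 2 mice the shares were not tested, and within each mouse the populations had different last digits of the library code. Pdgfra was detected in 83.8% and 97.0% of stem cells and 89.5% and 89.2% of tumour cells of mice 1 and 2. Olig2 was found in 54.1% and 54.5% of stem cells and 39.5% and 40.5% of tumour cells, and Sox2 in 16.2% and 21.2% against 21.1% and 27.0%. Pdgfb was found in 83.8% and 54.5% of stem cells and 73.7% and 78.4% of tumour cells, and Akt1 in 54.1% and 45.5% against 44.7% and 48.6%. The oligodendrocyte gene Mbp was found in 2.70% and 6.06% of stem cells and in 2.63% and 18.9% of tumour cells, and the neuroblast gene Dcx in 10.8% and 6.06% against 10.5% and 18.9%. Mki67 was found in 1, 1, 1 and 2 cells of stem mouse 1, stem mouse 2, tumour mouse 1 and tumour mouse 2, Top2a in 1, 1, 0 and 3, Gfap in 1, 2, 0 and 2 and Aqp4 in 0, 1, 0 and 0. Without thinning Mki67 was found in 1, 3, 7 and 8 cells of these groups, of which 1, 3, 1 and 2 had 10 or more counts. In the tumour cells of mice 1 and 2, 1 cell held 99.96% and 96.5% of the Mki67 counts. The larger tumour numbers thus rest on cells with few counts. Mbp was found without thinning in 5.41% and 21.2% of stem cells and 13.2% and 48.6% of tumour cells. Dcx was then found in 24.3% and 27.3% of stem cells and 15.8% and 27.0% of tumour cells. Akt1 was then found in 89.2% and 75.8% of stem cells and 57.9% and 73.0% of tumour cells. In mouse 2 the stem share of Akt1 thus turned from lower to higher than the tumour share. The microglial gene C1qa, which glioma cells should lack, was found in 0, 0, 0 and 1 cells of these groups, and without thinning in 0, 0, 1 and 2. The endothelial gene Cldn5 was found in 0 cells of each group, and without thinning in 1 stem cell of mouse 2, so the 0 counts at this depth set no limit on the share of cells with these genes. Median depths were 4484513 and 5093483 counts in the stem cells and 4457879 and 4381074 counts in the tumour cells of mice 1 and 2.

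**Figure D3:**
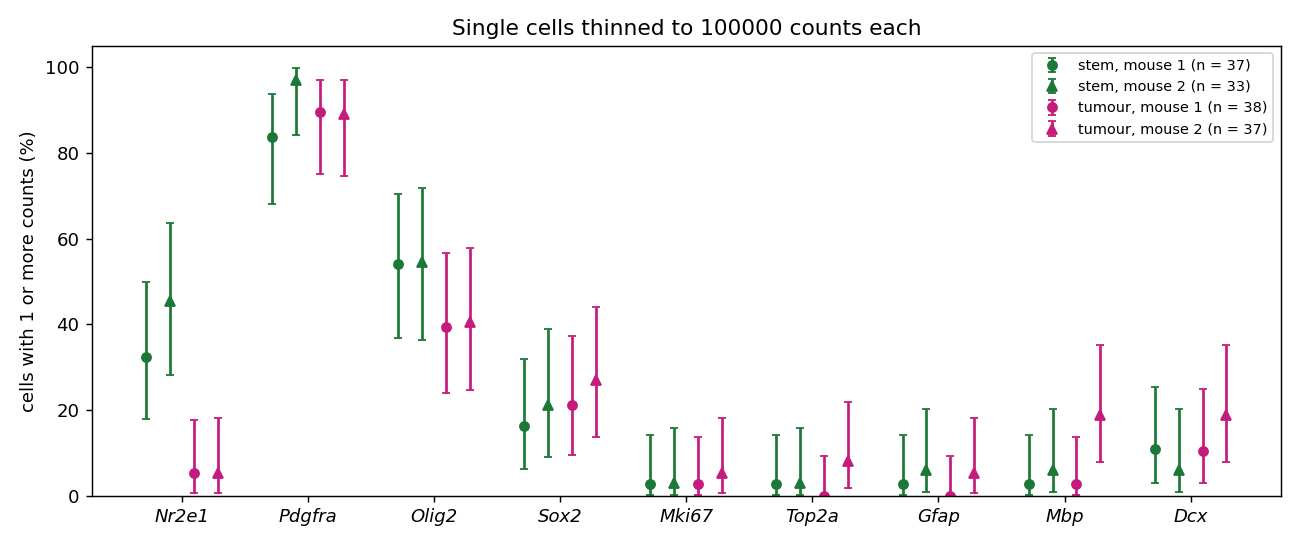
Share of cells with 1 or more counts of 9 genes after thinning to 100000 counts, per mouse and population, with exact 95% intervals for counting error. Nr2e1 lies at 32.4% and 45.5% in stem cells and at 5.26% and 5.41% in tumour cells, while Pdgfra is above 83% in every group.

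Most cells carried an oligodendrocyte-precursor profile: 81.1% and 93.9% of stem cells and 86.8% and 89.2% of tumour cells had at least 5 of the 16 precursor genes at 10 or more counts. Cells with at least 5 S phase genes at that level were 0 of 75 in mouse 1 and 17 of 70 in mouse 2 (24.3%, 14.8% to 36.0%), made up of 8 stem and 9 tumour cells. Cells with at least 5 genes of G2 and mitosis were 0 of 75 and 5 of 70 (7.14%, 2.36% to 15.9%), and no cycling rate was read from these counts. By markers, 2 cells were oligodendrocyte-rich and 1 was microglia-rich, all 3 in the tumour cells of mouse 2, and 1 stem cell of mouse 2 had 5 of 6 erythroid genes together with 12 precursor genes. No doublet caller was run. Clustering gave 4 groups that the markers did not name: 48 cells of mouse 2 alone, 45 cells of mouse 1 alone, 39 cells of both mice with a median of 2035 genes per cell, and 13 cells of both mice. The cluster with only mouse 2 cells held 24 of 33 stem and 24 of 37 tumour cells of that mouse, and the cluster with only mouse 1 cells held 26 of 37 and 19 of 38 of those of mouse 1. The mouse matched the cluster majority in 84.8% of cells and the population in 58.6%, while at a resolution of 0.5, with 2 clusters, both matched in 60.7%.

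**Figure D4:**
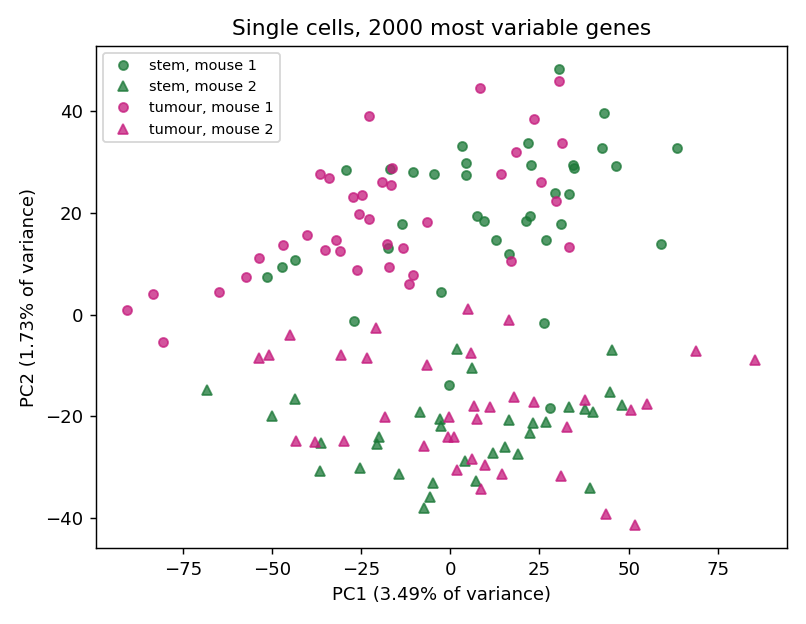
The 145 single cells on the leading principal components of the 2000 most variable genes, coloured by population, with circles for mouse 1 and triangles for mouse 2. Of the cells of mouse 1, 70 of 75 lie above 0 on PC2 (1.73% of variance), against 1 of 70 in mouse 2.

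Between the assays, expression levels were closer than fold changes. Across 10313 genes, which are not independent replicates, levels in the bulk tubes and the sums had a Spearman rho of 0.725 and 0.628 in the stem cells and 0.673 and 0.629 in the tumour cells of mice 1 and 2. Log2 changes had a rho of 0.0881 in mouse 1, the animal of the bulk tubes, and -0.00544 in mouse 2. Of 771 genes called in bulk and measured in the sums, 476 (61.7%) had the same direction in mouse 1, where random genes of like level gave 54.2% (95% of gene draws from 50.8% to 57.5%). In mouse 2 it was 352 (45.7%) against 48.9% (95% of gene draws from 45.5% to 52.3%).

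Rrm2 and the replicative helicase genes Mcm2 and Mcm3, and the chromosome Y genes Ddx3y and Eif2s3y, were higher in mouse 2 than in mouse 1 in both populations, in a comparison of 1 mouse with 1 mouse that has no replicates and was not tested. Of 3855 genes with at least 50 CPM in both sums of a mouse, 370 were at least 2-fold higher and 322 at least 2-fold lower in mouse 2 in both populations, while 1428 had opposite directions. The 10 highest were Rrm2, Ddx3y, Cul7, Mcm3, Mcm2, Pcdhb9, Eif2s3y, Trmt2a, Abcd4 and Mrpl10. Rrm2, a subunit of ribonucleotide reductase, was at 170 and 240 CPM in the stem and tumour sums of mouse 2, from 3 and 8 cells with 10 or more counts, and had 1 count in mouse 1. Mcm2 and Mcm3 were at 141 and 168 CPM in the stem sum of mouse 2. The 10 lowest were Rnf185, Sec31a, Gfpt2, Mt2, Mob1b, Lrig1, Msantd4, Hgh1, Klf15 and Slc25a15. Mt2, a metal-binding metallothionein gene, had 10 or more counts in 25 stem and 25 tumour cells of mouse 1 and in 2 and 0 cells of mouse 2, with 246 and 1.42 CPM in the stem sums. Each of the other genes named here had 10 or more counts in at most 8 cells of any sum. Genes of chromosome Y had 10 or more counts in 0 of 75 cells of mouse 1 and in 6 of 33 and 14 of 37 cells of mouse 2, and Xist in 1 and 2 cells of mouse 1 and in 0 of mouse 2. The bulk tubes, labelled mouse 1, held 7543 and 6108 counts of Xist and at most 1 count of any Y gene per library.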

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

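All tests of explanations in this part were chosen after the results were seen. A gap between 1 library and the rest of its group was looked for in 30 groups of values, and a difference between the mice in the 8 key genes.

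Mal in the stem tubes had 1 library far from the others: stem replicate 4 held 6.96 CPM against 0.622 to 0.689 CPM, a gap of 0.989 of the range. Ephb4 in the stem tubes had a gap of 0.871, with 24.8 CPM in stem replicate 4 and 13.5 to 14.9 CPM in the others. The critical value for 4 libraries is 0.829, and chance passes it in about 1 in 20 groups, so the count of 2 of 30 is near what chance gives. That count does not weigh the size of the Mal gap. The log2 change of Mog, another myelin gene, also became more negative without stem replicate 4, as given above.

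In the single cells, 4 key genes had opposite directions in the 2 mice, and the difference was not tested. The log2 ratio of stem to tumour sums was -1.78 in mouse 1 and 0.76 in mouse 2 for Sox2, and -0.042 and 1.61 for Olig2. For Pdgfb it was 0.80 and -1.33, and for Gfap 4.31 and -1.17, where Gfap rested on at most 2 cells with 10 or more counts in any sum.

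The 911 genes called between the bulk populations were compared with all 35 ways to split the 7 tubes into 4 and 3. Only 1 split, the real one, gave as many, and the highest other split gave 2 genes, so the calls followed the sorted populations. A share of 1 in 35 is the lowest that this comparison can give. The other splits mix the populations, which widens the spread within their groups. They cannot exclude a difference in sorting or handling between the tubes of the populations.

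Oligodendrocyte genes, of which 11 of 13 listed were measured in these tubes and 0 are on another list, were lower in the stem tubes (adjusted p = 0.184 with an estimated correlation), and a candidate explanation is a few oligodendrocytes among the sorted tumour cells. The mean of 2 oligodendrocyte-rich tumour cells of mouse 2 was taken as the profile. With it, 6 of the 8 called genes of the list needed a share within 3 times the median. That median was 0.623% of the counts. It equals 6.23 cells in a tube of 1000 only if oligodendrocytes and tumour cells hold equal amounts of RNA, which was not measured. A few oligodendrocytes could thus give the tube means of these 6 genes. Plp1, the most abundant and at 292 CPM in the stem tubes as well, needed 0.587% and Mbp 0.467%, while Mog needed 0.127% and Ugt8a 24.4%, and off the list Trf needed 0.309%, Car2 0.467%, Ptgds 2.83% and Apod 113%, where the 2 cells held 719 and 0 CPM of Apod, so its source stays open. Between the tumour tubes Trf ranged from 29 to 235 CPM and Plp1 from 743 to 987 CPM. Mal ranged from 18.2 to 46.7, Mag from 17.3 to 30.2 and Mog from 9.6 to 13.4 CPM. All fell in the same order of tubes. Added cells of a fixed profile would change Trf and the Plp1 excess over the stem tubes in equal proportion, and these ranges differ. The shares rest on tube means and do not test this. The rule was set after rough shares had been seen, and the profile comes from the other mouse, from cells picked by the markers of this same list. The shares therefore cannot tell stray oligodendrocytes from RFP positive cells of a like profile. A gate on RFP would remove oligodendrocytes that do not descend from infected cells. A difference between the populations themselves, in which RFP positive cells mature into oligodendrocytes, stays open and was not tested.

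Oligodendrocyte-precursor genes were also lower in the stem tubes, with 11 of 16 called (adjusted p = 0.184 with an estimated correlation). Cells with the profile of the 2 oligodendrocyte-rich cells, added to the tumour tubes, would not give this. Added cells raise a gene only where they hold more of it than the rest, and all 11 called genes lay below their stem tube mean in both oligodendrocyte-rich cells, with Pdgfra at 0.211 and 0.457 CPM against 2538 CPM. These are 2 cells of the other mouse, picked by oligodendrocyte markers. They held 1 and 3 precursor genes by the same count threshold. The outcome thus largely followed from the choice of cells and is not an independent test. Added cells of another profile were not tested. A difference between the populations stays open and was not tested.

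Hmox1 and Slc7a11, both targets of the oxidative stress factor NRF2, were among the highest genes of the stem tubes, and an NRF2 programme in that population may be the reason. Of 19 other NRF2 targets, 10 rose and 0 fell, with a median log2 change of 0.42. They were listed after the bulk values were seen and without the genes that drew attention. Their camera p with an estimated correlation was 0.0157, not adjusted for other lists. The planned neural stem and G2 and mitosis lists had lower unadjusted values, 0.00297 and 0.0125, and did not pass once adjusted. Txnrd1 rose by 0.74 ± 0.09 and Gsr by 0.68 ± 0.13, while Nqo1 had a log2 change of -0.18 ± 0.39, or 0.024 without tumour replicate 4. Handling stress in the stem tubes cannot be told apart from an NRF2 programme. The immediate-early list had a median of 0.14 (bootstrap interval -0.01 to 0.37). Its camera adjusted p was 0.0771 with the preset correlation, and its unadjusted camera p with an estimated correlation was 0.221. The labels do not say whether tubes of both populations were handled together. Both explanations are hypotheses found and tested on the same tubes of 1 mouse. In the single-cell sums Hmox1 was higher in the stem cells of mouse 1 and lower in those of mouse 2, from few cells.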

How the results depend on the processing

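The fit without marker-rich cells was chosen after seeing the data, the other alternatives before. In bulk, 436 of 447 values of named genes kept their direction and side of the threshold and 11 lost the call, for Nr2e1, Mki67, Gfap, Mal and Cdh18. Of 845 values of list members and other genes named, 728 kept both, 115 lost the call, 1 gained it (Xist) and 1 reversed: Nqo1, not called, ranged from -0.33 to 0.024 when a library was left out, the latter without tumour replicate 4. By limma on TPM without a filter the adjusted p was 0.139 for Top2a, 0.647 for Cenpf, 0.135 for Sox9, 0.128 for Cspg5 and 0.222 for Aqp4, and the cause was not tested. The 911 bulk calls became 518 and 466 by limma on TPM with offsets of 1 and 0.1 and 290 without a filter, and 576 to 827 when a library was left out, the lowest without tumour replicate 2. The cause was not tested, beyond fewer libraries in the last case. With the replicate number as a block 690 were called, 634 of them among the 911, and with library totals alone 945, of which 559 were higher and 386 lower. Without the low-count filter 1236 of 24649 tested genes were called, 596 higher and 640 lower, so the majority changed from higher to lower. DESeq2 called 891 genes in the sums where the 13 other alternatives called 0. Of the 8 bulk lists, 0 passed with an estimated correlation. In the sums 0 to 4 lists passed when 1 sum was left out, which leaves a population with 1 sum assumed to vary like the other. Resolutions of 0.5 and 2 gave 2 and 14 clusters, with the mouse matched in 60.7% and 86.2% of cells. No cluster was named, so the fit without named clusters gave no value.

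No key gene of the sums was called by edgeR, and these directions reversed. With code suffix and mouse as covariates, log2 changes were -3.39 for Nr2e1, -1.42 for Olig2, -0.61 for Pdgfra and -0.27 for Akt1, in a fit with 1 residual degree of freedom whose median over all genes was -5.49, so each lay above that median. Without marker-rich cells Pdgfb had a log2 change of 0.061. When 1 sum was left out, Sox2 ranged from -1.47 to 0.35, Pdgfb from -1.01 to 0.44 and Gfap from -0.59 to 14.20, and the cause was not tested. Of the shares of cells, 108 of 128 stayed within their interval.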

Other observations

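The tests of the protocadherin genes and the look at single genes in this part were chosen after the values were seen.

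The clustered protocadherins are cell-surface adhesion genes whose isoforms give neural cells distinct identities. Those of the alpha and gamma clusters were called more often than other genes between the bulk populations, and those of the beta cluster were not. Of 51 tested over all clusters, 13 passed (25.5%), 7 higher and 6 lower in the stem tubes, against 6.98% of the other genes (Fisher's exact test, 2-sided, p = 3.76e-05, with genes not independent). Without Pcdhga12 and the 2 entries named Pcdha11, which drew attention to the clusters, 10 of 48 passed (20.8%, p = 0.00158). In the gamma cluster 7 of 22 passed, 3 higher and 4 lower, while the sum of the cluster was 1591 ± 70.4 CPM in the stem tubes (n = 4) and 1503 ± 38.5 CPM in the tumour tubes (n = 3). In the alpha cluster 5 of 10 passed, 4 higher and 1 lower, with sums of 93.1 ± 10.8 and 73.9 ± 1.27 CPM. In the beta cluster 1 of 19 passed (5.26%), which was lower, with sums of 360 ± 11.0 and 401 ± 36.2 CPM. The sums were not tested. Members of the alpha and gamma clusters, which hold the excess of calls, share exons and reads. The values of single members and the test over all clusters are therefore uncertain.

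The clusters found in the single cells differed by named genes. The cluster of mouse 2 cells had higher mean levels of Gpr17 and C1ql1, genes of the oligodendrocyte-precursor list, by 4.07 and 3.67 on the log2 scale, and of the cyclin gene Ccnd1 by 3.63. The cluster of mouse 1 cells had higher levels of the metallothionein genes Mt1 and Mt2, by 4.47 and 4.49, and of Aldoc, a gene of the astrocyte list, by 3.71. Cells of both clusters had a median of 4 astrocyte genes at 10 or more counts. These differences describe the clusters they were chosen from and were not tested.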
